A study of Bacillus subtilis with 6 samples.

How the data were processed

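The data are 2-colour Agilent microarrays of 6 RNA samples of Bacillus subtilis 168, 3 from cultures treated with air plasma and 3 from control cultures, which the labels describe as biological replicates. Per the labels, each sample was labelled with Cy5 and hybridised together with a reference pool labelled with Cy3, which the labels describe as equal amounts of RNA of all samples. The dyes were not swapped, so a bias between the dyes stays in every ratio to the pool. The part of it that is the same in every array cancels in the comparison of the groups, since all arrays share the orientation. A part that varies with signal level need not cancel. Direction was taken from the dyes, as sample over pool.

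A gene table and a probe table were used. Per the file headers, the gene table holds the error-weighted average of the probe ratios of each SubtiList gene, made by the authors with Rosetta Resolver 7.2.1, as a linear ratio of sample to pool. The deposited probe table holds values on a log10 scale for 41882 probes. Agilent Feature Extraction 10.5 is named in the submitters' processing notes. The base of 10 was inferred here, because the quartiles of the probe values lie close to those of log10 of the gene ratios. The columns of the probe table have medians of 0.00402, 0.00825 and 0 in controls 1 to 3 and 0, 0.000466 and 0 in air plasma 1 to 3. Any centring or filtering of either table, and the genome build, are not given in the sources used here. Error-weighted averaging favours bright probes, and averaging of probes narrows the spread of a gene. Signal levels were not analysed here, so the distance of a ratio from background is unknown, and only the number of arrays is said to limit the precision. Exact log ratios of 0 stand in all 6 arrays for 1514 probes and in at least 1 array for 6288, and 31 genes have a ratio of exactly 1 in at least 1 array.

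The probe table pairs no probe with a gene, so probes were tested but not named. Of the 4105 locus tags of the gene table, 4037 matched the annotation of assembly ASM904v1 and 68 did not. That assembly was used only for current gene symbols and for the order of neighbouring genes, and no coordinates are given. The file's gene name is used, with the current symbol in parentheses where it differs and is helpful. In all, 1018 names differ from the current symbol.

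Gene ratios were put on a log2 scale without further scaling or pseudocount, and all 6 arrays were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with group as the only term. Probe values were converted to log2 and fitted alike. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes or all probes and a threshold of 0.05. A fold is 2 to the power of the fitted log2 change, and errors of log2 changes are standard errors from the fit. Before use, the fits were tested on simulated data with 50 changed genes or probes at each of 4 log2 sizes. At log2 changes of 0.5, 1, 2 and 4 the gene fit recovered 46%, 86%, 94% and 100% of those in 4105 genes, with 14 false calls. The probe fit recovered 0%, 36%, 90% and 92% in 41882 probes, with 8 false calls. Each simulation changed 200 genes or probes, with independent noise, whereas 2049 genes were called in the data. These rates therefore need not hold for the data.

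The test, the gene lists and the naming rule were set before the data were examined. The 42 lists are textbook regulons and pathways of this bacterium: PerR, Spx, CtsR, HrcA, CssRS, sigma B, LexA, base excision repair, the SPbeta and PBSX prophages, ICEBs1, CymR, sulfate assimilation, S-box genes, Fur, CsoR, CzrA and ArsR, Zur, MntR, quinone and organic peroxide responses, the oxygen and nitric oxide regulators, ribosomal proteins, ATP synthase, purines, pyrimidines, glycolysis, the citric acid cycle, synthesis of arginine, histidine, tryptophan and branched-chain amino acids, motility, competence, early sporulation, sigma W, sigma M, LiaRS, FapR, TnrA with GlnR, CcpA, translation with RNA polymerase, and surfactin. The lists for motile, competent and sporulating cells stand for kinds of cells that a culture can hold. Only yorB, yorC and yraA belong to more than 1 list. Lists were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and with fry. Members were counted as called over all genes and again with p adjusted over the list alone.

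Genes were named by rule: per direction the 15 largest absolute log2 changes among called genes whose 3 values in each group do not overlap, from each list the 2 largest absolute changes among called members, or among all members where fewer were called, and 30 genes fixed by name. The rule allowed up to 4 members of a list without saying how members 3 and 4 are chosen. Its ranking was carried on to them after the data were examined, so the 71 of 190 genes that are named only as members 3 or 4 count as chosen after their values were seen. Other names are marked in the text as chosen in that way.

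Alternatives were the replicate number as a block, each array left out in turn, quantile normalization, median centring, robust priors, a pseudocount of 16 added to the ratio, array weights, an equal-variance test for each gene, an adjusted p under 0.01, minimum folds of 1.5 and 2, a test against a minimum fold of 1.5 (treat), an estimated correlation in camera, and fry. Leaving out genes at exactly 1 and probes at exactly 0 was chosen after seeing the data. Other splits of the arrays into 3 and 3 were refitted as well. With groups of 3, no test for outlying samples was made. The fitted array weights were lowest for air plasma 1 (0.277) and highest for air plasma 2 (3.06).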

Results

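Transcript levels were measured in the wild-type laboratory strain Bacillus subtilis 168, grown with aeration in rich LB medium at 37 °C. At an optical density of 0.5, cultures were exposed for 15 min to air plasma, an electrical discharge in air that produces reactive oxygen and nitrogen species, at a discharge power of 7.4 W. Cells were sampled 5 min later. For the control cultures no mock treatment or sampling time was recorded here. Handling, aeration and time in culture can therefore not be told apart from the plasma itself. The data comprise 3 air plasma arrays and 3 control arrays, each from a biological replicate. Every array gave the ratio of 1 sample to a common reference pool, so the number of arrays limits the precision of each value. Ratios were available for 4105 annotated genes, and the median ratio of an array lay between 1.02 and 1.05. Across genes, which are not independent replicates, the log2 ratios of control arrays correlated with r from 0.866 to 0.959. Air plasma arrays correlated with each other with r from 0.820 to 0.897, and arrays of different groups with r from 0.00872 to 0.313.

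The comparison asked which transcripts differed between air plasma and control cultures. Most or all genes of peroxide, quinone, thiol, DNA damage and tryptophan responses rose. Most or all genes of surfactin synthesis, nucleotide synthesis, motility and the ribosome fell. With limma and a Benjamini-Hochberg adjusted p under 0.05, 2049 of 4105 genes (49.9%) changed, 1012 higher and 1037 lower after air plasma. Of these, 394 were at least 2-fold higher and 207 at least 2-fold lower. In 2579 genes (62.8%) all 3 air plasma values lay on one side of all 3 control values, where chance gives 10%. The median log2 change of all genes was -0.03, which scaling of the arrays before deposit can fix, so it does not show that the centre stayed in place. After quantile normalization 949 genes were higher and 1152 lower, of which 345 were at least 2-fold higher and 279 at least 2-fold lower. Without control 1 the lower calls numbered 690 and the higher calls 813. Where 5 or fewer members of a list were called in a direction, those outside the naming rule (grpE, prmA and rsmE as yqeT and yqeU, yitT, ylxP, nth, polA, xre, yrpE, nasE, nasF, rplI, spoIIP, spoIIGA, spoIID, ddl, ywtF, accA, pucR, nrgB, yccC, ureA, ureB, gntP and gntZ) were named after their values were seen, as were members 3 and 4 of each list.

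**Figure D1:**
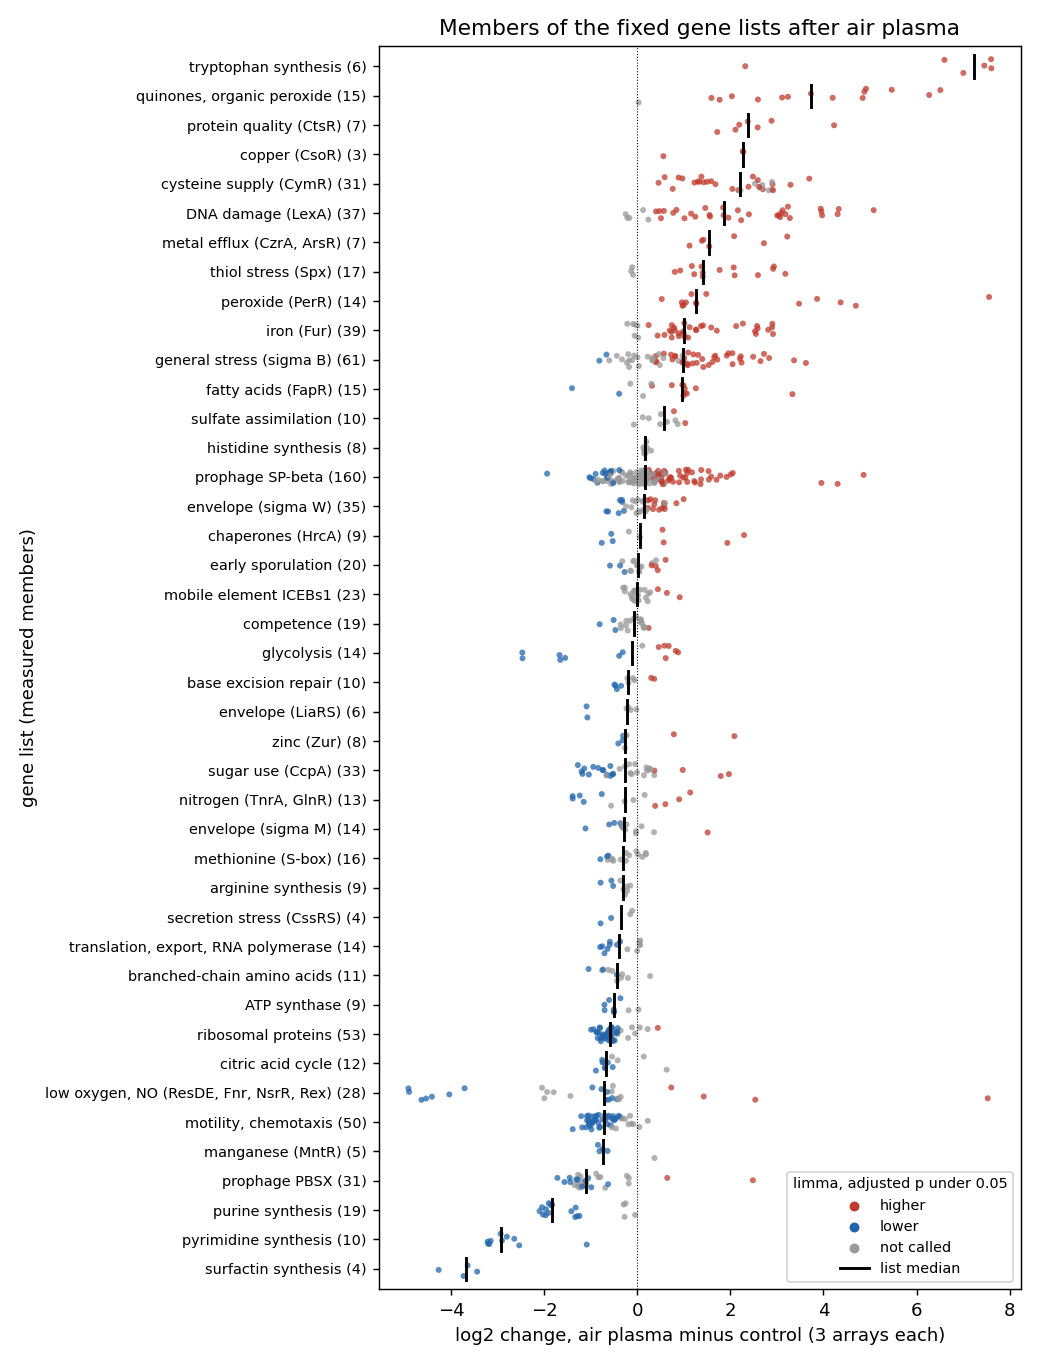
Log2 change of each measured member (points) of 42 gene lists on the horizontal axis, air plasma minus control with 3 arrays each, with a bar at each list's median; red and blue points were called higher and lower by limma, and grey points were not called. The tryptophan synthesis list has the highest median, 7.23, and the surfactin list the lowest, -3.69.

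All 14 measured genes of the PerR regulon, the peroxide response of this bacterium, rose (14 adjusted over the list alone), with a median log2 change of 1.27. The vegetative catalase katA (BSU08820) had a mean ratio of 0.0161 ± 0.0029 in control and 3.09 ± 0.94 after air plasma (SD, n = 3 each). Its log2 change of 7.56 ± 0.24 (SE) corresponds to 188-fold (limma, adjusted p = 7.80e-06). The DNA-protecting protein gene mrgA rose 25.9-fold, and ahpC and ahpF of alkyl hydroperoxide reductase rose 20.6-fold and 14.5-fold. Of 15 genes that answer to quinones, aldehydes, hypochlorite or organic peroxides under YodB, MhqR, OhrR and related repressors, 14 rose (14 adjusted over the list alone), with a median of 3.73. The putative dioxygenase genes ydfO (6.51 ± 0.31) and ykcA (mhqA, 4.91 ± 0.22) rose, as did the nitroreductase gene ydfN (6.27 ± 0.34). The organic hydroperoxide resistance gene yklA (ohrA) rose by 5.47 ± 0.21 on the log2 scale. By camera the peroxide list gave an adjusted p = 1.23e-08, and adjusted p = 0.620 with an estimated correlation. The quinone list gave an adjusted p = 1.59e-09 by camera, and adjusted p = 0.620 with an estimated correlation. Outside these lists, hxlB (7.62 ± 0.15) and hxlA (7.43 ± 0.14), whose products fix formaldehyde into sugar phosphates, and the flavin oxidoreductase gene yqjM (4.99 ± 0.11) were among the 15 largest rises.

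Most genes of the Spx regulon and all measured genes of the CtsR regulon rose as well. Of 17 genes of the Spx regulon and bacillithiol synthesis, which act on disulfide stress, 14 rose and 3 were not called (14 adjusted over the list alone), with a median log2 change of 1.41. Thioredoxin (trxA) rose 7.65-fold, thioredoxin reductase (trxB) 3.41-fold and the flavin reductase gene nfrA 9.07-fold. All 7 genes of the CtsR regulon, which encodes the Clp protease machinery, rose (7 adjusted over the list alone), led by clpE (18.7-fold) and clpC (7.38-fold), with ctsR itself 4.32-fold higher. By camera the Spx list gave an adjusted p = 4.45e-06, and adjusted p = 0.620 with an estimated correlation. The CtsR list gave an adjusted p = 6.54e-05 by camera, and adjusted p = 0.620 with an estimated correlation. The 9 HrcA-controlled genes divided, with 4 higher and 3 lower (4 and 3 adjusted over the list alone). The chaperonin genes groES and groEL rose 4.91-fold and 3.82-fold, dnaK rose 1.48-fold and grpE by 0.54 on the log2 scale. In the same operon yqeV (mtaB), a tRNA modification gene, fell 1.70-fold, and the methyltransferase genes yqeT (prmA, -0.53) and yqeU (rsmE, -0.56) fell as well. The HrcA list was not called as a group (camera, adjusted p = 0.692).

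Of 37 LexA-controlled genes, the SOS response to DNA damage, 32 rose and none was called lower (33 higher and 2 lower adjusted over the list alone), with a median log2 change of 1.86. The cell division inhibitor gene yneA rose 33.8-fold (5.08 ± 0.11) and dinB 20.1-fold. The excinuclease gene uvrB rose 8.23-fold, the repressor gene lexA 5.27-fold, from a ratio of 0.527 ± 0.014 to 2.78 ± 0.08 (SD, n = 3 each), and recA 4.70-fold. By camera this list gave an adjusted p = 5.20e-15, and adjusted p = 0.620 with an estimated correlation. Of 10 genes of base excision repair and removal of oxidised bases, 2 were higher and 4 lower (2 and 4 adjusted over the list alone). The higher genes were mutM (0.37) and polA (0.30), and neither call was kept without control 1, 2 or 3. The lower genes were mutT (nudT, -0.49), yfhQ (mutY, -0.47), exoA (-0.44) and nth (-0.34), and 2 of these calls were kept without control 1 or 2. The list was not called (camera, adjusted p = 0.201).

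Genes of the resident mobile elements were counted for each element. Of 160 genes of the SPbeta prophage region, 48 rose and 17 fell (48 and 14 adjusted over the list alone). The largest rises were in yolD (29.1-fold) and in yorC (19.8-fold) and yorB (15.5-fold), the last 2 of which the LexA list also holds. The SPbeta list had a median of 0.16 (camera, adjusted p = 0.0143), and adjusted p = 0.620 with an estimated correlation. Without air plasma 2 its camera adjusted p was 0.0944, and its lower calls numbered 9 without control 1, 7 without control 2, 11 without control 3, 10 without air plasma 1 and 27 without air plasma 2. Of 31 genes of the defective prophage PBSX, 2 rose and 11 fell. Adjusted over the list alone, 2 rose and none fell. The rises were in xkdA (5.60-fold) and the repressor gene xre (0.65), while xhlB (-1.71 ± 0.47) and xlyA (-1.56 ± 0.42), which act in cell lysis, fell. Their adjusted p was 0.0818 and 0.0744 without control 1, and 0.0757 and 0.0674 without control 2. The 11 lower PBSX calls became 0 without control 1 or control 2, 3 without air plasma 1 and 5 without air plasma 3. They became 14 without control 3 and 13 without air plasma 2. The PBSX list had a median of -1.11 (camera, adjusted p = 0.00640), with adjusted p = 0.692 with an estimated correlation and adjusted p = 0.350 with fry. With the replicate number as a block, the camera adjusted p of this list was 4.86e-07. Its median was -0.71 without air plasma 3. In control 3 its median lay 0.81 below that of controls 1 and 2 on the log2 scale. Of 23 genes of the conjugative element ICEBs1, 3 rose (2 adjusted over the list alone), with ydcL at 1.88-fold, ydcM (immA) at 1.56-fold and ydcN (immR) at 1.36-fold, the last with an adjusted p from 0.0756 to 0.0948 without any 1 array other than air plasma 1. The ICEBs1 list was not called (camera, adjusted p = 0.575), and its median (-0.004) and mean (0.07) differed in sign.

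The general stress regulon of sigma B also rose in large part. Of 61 genes, 39 were higher and 2 lower (40 and 2 adjusted over the list alone), with a median log2 change of 0.97, and the lower calls, yitT (-0.81) and ylxP (-0.66), became 5 without control 2. The hydrophilic stress protein gene gsiB rose 12.3-fold and yflT 10.3-fold. The sigB gene itself rose 1.99-fold, and the ribosomal stress gene ctc had a log2 change of -0.18 ± 0.14 (limma, adjusted p = 0.315). The stress catalase gene katE rose by 1.96 ± 0.49, and its adjusted p was 0.0509 without air plasma 1. By camera this list gave an adjusted p = 3.40e-06, and adjusted p = 0.652 with an estimated correlation. In control 3 the sigma B median lay 0.40 above that of controls 1 and 2 on the log2 scale.

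Genes of envelope responses were called in both directions. Of 35 sigma W genes, 13 were higher and 7 lower (13 and 7 adjusted over the list alone), with yuaF (2.00-fold higher) and racX (1.58-fold lower) among the largest changes. The higher calls numbered 6 without any of the 3 controls or air plasma 2, and the lower calls 3, 2 and 3 without controls 1, 2 and 3. The sigW gene had a log2 change of 0.01 ± 0.09, and the list was not called (camera, adjusted p = 0.201). In the LiaRS list, 2 of 6 genes fell (2 adjusted over the list alone), yvqI (liaI) 2.13-fold and yvqH (liaH) 2.10-fold. In the CssRS list, 2 of 4 fell (2 adjusted over the list alone), the surface proteases htrA (1.73-fold) and yvtA (htrB, 1.48-fold). In the sigma M list, 1 of 14 rose and 5 fell (1 and 5 adjusted over the list alone), with murB 2.16-fold lower, yfnI (ltaSA) 1.52-fold, murF 1.41-fold, and ddl (-0.36) and ywtF (tagT, -0.32) lower too. The lower calls numbered 9 without air plasma 1. The higher gene, yacK (disA, 2.85-fold), lies within a run of 7 higher neighbouring genes that also holds ctsR and clpC. These lists were not called by camera (adjusted p = 0.0745 for LiaRS, 0.0797 for CssRS and 0.0840 for sigma M). LiaRS was called without control 3 (0.0410), and CssRS (0.0431) and sigma M (0.0142) without air plasma 1. Genes of the fatty acid list, named for FapR, moved more, with 10 of 15 higher and 2 lower (11 and 2 adjusted over the list alone). A place in this list does not by itself show control by FapR. The initiating synthase gene fabHB rose 10.1-fold and fabF 2.39-fold, and the fatty acid desaturase gene des fell 2.64-fold. The des call was kept without each array in turn, and the other lower call, accA (-0.39), was lost without control 1, control 2, air plasma 1 or air plasma 2. The FapR list had a median of 0.97 (camera, adjusted p = 0.00173), and adjusted p = 0.620 with an estimated correlation.

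Most genes for cysteine supply under CymR rose, and 1 control array stood apart in them. Of 31 genes controlled by CymR, the repressor of cysteine and sulfur compound uptake, 24 rose and 7 were not called (25 higher adjusted over the list alone), with a median log2 change of 2.22. The cystathionine beta-synthase and lyase genes yrhA (mccA) and yrhB (mccB) rose 7.50-fold and 9.79-fold, and yrrT rose 12.9-fold, with an adjusted p of 0.0545 without control 1. Without control 3 the log2 changes of yrhA, yrhB and yrrT were 3.58, 4.004 and 4.74, against 2.91, 3.29 and 3.69 with all arrays, and that of yrrT was 2.94 without control 2. The cysteine synthase gene cysK rose 4.12-fold (2.04 ± 0.44). Its ratio was 0.408, 0.392 and 1.14 in controls 1, 2 and 3, and 3.14, 1.92 and 2.13 after air plasma. Over the whole CymR list, control 3 lay a median of 1.52 above controls 1 and 2 on the log2 scale, and 19 of 31 members lay more than 1 above. Without control 3, 30 of 31 members were called higher, and 16 without control 1, 18 without control 2, 17 without air plasma 1 and 19 without air plasma 2 or air plasma 3. By camera the CymR list gave an adjusted p = 1.79e-07, and adjusted p = 0.620 with an estimated correlation. Of 10 sulfate assimilation genes, 2 rose (none adjusted over the list alone), yvgR (cysJ, 1.03 ± 0.29) and yvgQ (cysI, 0.79 ± 0.22), both of which encode sulfite reductase subunits. There control 3 lay a median of 1.59 above controls 1 and 2. This list was not called (camera, adjusted p = 0.181), but without control 3 it was (adjusted p = 0.00110), with 8 genes higher, while none was higher without control 1, control 2, air plasma 1 or air plasma 3. Of 16 S-box genes of methionine synthesis and salvage, 3 fell (1 adjusted over the list alone), with S-adenosylmethionine synthetase (metK) 1.53-fold and the salvage genes ykrV (mtnE) 1.73-fold and ykrZ (mtnD) 1.57-fold lower. The S-box list was not called (camera, adjusted p = 0.0985), but without air plasma 1 it was (adjusted p = 0.00203), with 9 genes lower. Leaving out any other array left 1 lower call.

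Genes of metal regulons were called in both directions. With all arrays, the metal lists called by camera all rose. Of 39 genes of the Fur regulon for siderophores and iron uptake, 33 rose (33 adjusted over the list alone), with a median log2 change of 1.01, and the bacillibactin synthesis genes dhbA and dhbE rose 7.55-fold and 7.47-fold. All 3 copper genes under CsoR rose (3 adjusted over the list alone), with the efflux ATPase gene yvgX (copA) 4.81-fold higher. All 7 genes of the CzrA and ArsR list for cadmium, zinc and arsenic efflux rose (7 adjusted over the list alone), with yvgW (cadA) 9.33-fold and czcD 6.59-fold higher. By camera these lists gave adjusted p values of 3.50e-09 for Fur, 0.0175 for CsoR and 9.74e-04 for CzrA and ArsR, each with adjusted p = 0.620 with an estimated correlation. Of 5 manganese uptake genes under MntR, 4 fell (1 higher and 4 lower adjusted over the list alone), with mntD (1.79-fold) and mntC (1.76-fold) the largest falls. The transporter gene mntH, chosen after its value was seen, had a log2 change of 0.37 ± 0.13 and was not called (limma, adjusted p = 0.0564), while 1 gene was called higher without air plasma 2. The MntR list was not called (camera, adjusted p = 0.0988), but was without control 1 (0.0432). Of 8 Zur genes for zinc, 2 rose and 3 fell (2 and 3 adjusted over the list alone), with the alternative ribosomal protein genes yhzA (rpsNB) 4.25-fold and ytiA (rpmEB) 1.72-fold higher. The falls were in the zinc transporter gene yceA (znuB, 1.33-fold), yciB (1.24-fold) and yrpE (zinT, -0.30). The yciB call was lost without control 1, control 2, air plasma 1 or air plasma 2 (adjusted p from 0.0520 to 0.103), and the lower Zur calls numbered 1 without control 2. The Zur list was not called (camera, adjusted p = 0.550), and its median (-0.26) and mean (0.14) differed in sign.

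All 6 measured genes of tryptophan synthesis rose (6 adjusted over the list alone), with a median log2 change of 7.23, the highest of the 42 lists. The ratio of trpC went from 0.0177 ± 0.0011 to 3.82 ± 2.0 (SD, n = 3 each), a log2 change of 7.60 ± 0.39, and trpF (7.60 ± 0.36) and trpD (7.45 ± 0.45) were close to it, with trpB 128-fold higher. By camera this list gave an adjusted p = 2.93e-05, and adjusted p = 0.620 with an estimated correlation. The neighbouring genes aroE (1.77), tyrA (2.14) and hisC (2.20) of aromatic amino acid and histidine synthesis, chosen after their values were seen, rose as well. The lists for histidine, arginine and branched-chain amino acids held no higher call. No histidine synthesis gene among 8 was called (none adjusted over the list alone, and camera adjusted p = 0.467), with hisZ the largest change at 0.30 ± 0.25, which ranged from 0.08 without air plasma 1 to 0.50 without control 3. In control 3 the histidine median lay 0.53 above and the arginine median 0.36 below that of controls 1 and 2 on the log2 scale. In arginine synthesis, 3 of 9 genes fell (3 adjusted over the list alone), with carB 1.73-fold, argD 1.47-fold and carA 1.43-fold lower. The argD and carA calls were lost without control 1, air plasma 2 or air plasma 3, and that of carA also without control 2 (adjusted p from 0.0537 to 0.0908). In the synthesis of branched-chain amino acids, 3 of 11 fell (3 adjusted over the list alone), with ilvD 2.06-fold, leuD 1.66-fold and ybgE (ilvE) 1.35-fold lower. The leuD call was lost without control 1, control 3, air plasma 2 or air plasma 3 (adjusted p from 0.0561 to 0.0807). Both lists were called by camera (adjusted p = 0.0486 each), and both had adjusted p = 0.652 with an estimated correlation. The arginine call was lost without control 1, control 2, air plasma 2 or air plasma 3 (adjusted p from 0.0763 to 0.114), after quantile normalization (adjusted p = 0.0550) and with fry (adjusted p = 0.0747). The branched-chain call was lost without control 1, control 3, air plasma 2 or air plasma 3 (adjusted p from 0.0763 to 0.122), and with fry (adjusted p = 0.0644). Lower calls ranged from 1 to 6 in the arginine list, highest without control 3, and from 2 to 5 in the branched-chain list, highest without control 2 or air plasma 1.

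Targets of regulators that read oxygen, nitric oxide and redox state went in both directions. Of 28 genes under ResDE, Fnr, NsrR or Rex, 4 rose and 14 fell (4 and 21 adjusted over the list alone). The nitric oxide detoxifying flavohaemoglobin gene hmp rose 184-fold, from a ratio of 0.027 ± 0.014 to 4.58 ± 0.23 (SD, n = 3 each), and ykjA, which lies close to hmp on the chromosome, rose by 5.95 ± 0.14 on the log2 scale. The nitrite reductase genes nasD (5.79-fold) and nasE (1.43 on the log2 scale) rose, as did nasF (0.73). The falls were led by cytochrome bd oxidase (cydA, 30.1-fold, and cydB, 21.2-fold), lactate dehydrogenase (ldh, 29.9-fold), the lactate permease gene lctP (24.8-fold) and the nitrite transporter gene ywcJ (nirC, 23.2-fold). The nitrate reductase gene narG, chosen after its value was seen, had a log2 change of -1.79 ± 0.66 and was not called (limma, adjusted p = 0.0617). The list had a median of -0.72 (camera, adjusted p = 0.00173), and adjusted p = 0.652 with an estimated correlation. Of 13 TnrA and GlnR targets for nitrogen limitation, 4 rose and 5 fell (4 and 5 adjusted over the list alone), with glutamine synthetase (glnA) 2.61-fold and the ammonium transporter gene nrgA (amtB) 2.62-fold lower. The other falls were in glnR (2.35-fold), nasA (2.22-fold) and pucR (-0.76), and the rises in ureA (1.14), nrgB (glnK, 0.90), ureB (0.60) and yccC (ansZ, 0.39). This list was not called (camera, adjusted p = 0.575).

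**Figure D2:**
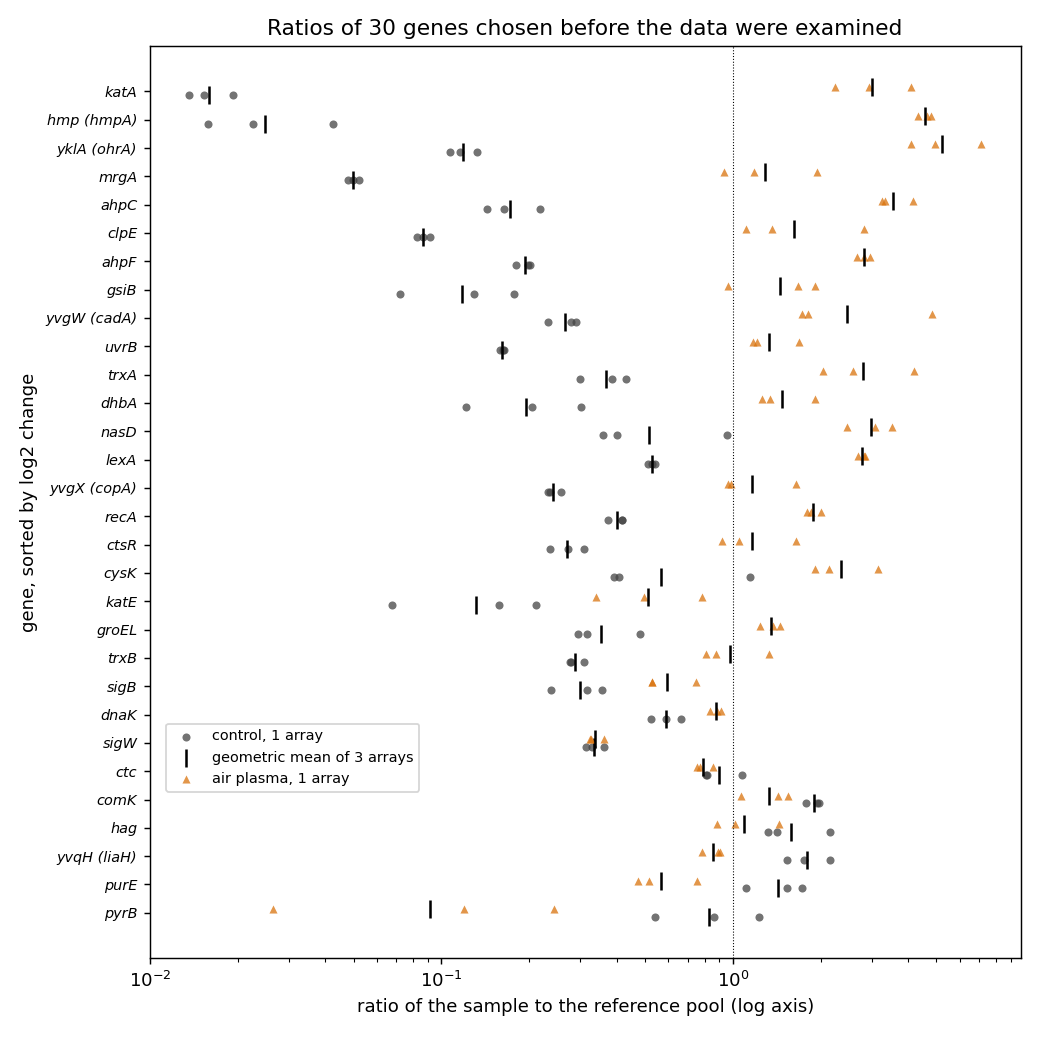
Ratio of the sample to the reference pool in each array (log axis; circles, control; triangles, air plasma) for 30 genes chosen before the data were examined, sorted by log2 change, with bars at the geometric mean of 3 arrays. The air plasma values of katA lie between 2.24 and 4.10 and its control values between 0.0137 and 0.0193, while those of sigW overlap.

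Most nucleotide synthesis genes fell. All 10 genes of the pyrimidine operon were lower (10 adjusted over the list alone), with a median log2 change of -2.92, and pyrB fell by 3.18 ± 0.80 (limma, adjusted p = 0.0177) and pyrC by 3.21 ± 0.86. Without air plasma 3 the log2 changes were -2.28 for pyrB, -2.21 for pyrC and -2.06 for the list median, and without air plasma 2 they were -3.88 for pyrB and -3.93 for pyrC. The air plasma ratios of pyrB spread from 0.0265 to 0.244. The 10 calls became 1 without control 1, 3 without control 2 and 6 without control 3, and the adjusted p of pyrB and pyrC was 0.0636 and 0.0747 without control 1 and 0.0525 and 0.0634 without control 2. Of 19 genes of the PurR regulon for purine synthesis, 15 fell (16 adjusted over the list alone), with a median of -1.83, and the transporter gene ytiP (pbuO, -2.10 ± 0.12) and purN (-2.04 ± 0.40) were the largest falls. The purE gene fell 2.52-fold. By camera the pyrimidine list gave an adjusted p = 0.00441, and adjusted p = 0.652 with an estimated correlation. The purine list gave an adjusted p = 2.58e-05 by camera, and adjusted p = 0.620 with an estimated correlation. In control 3 the purine median lay 0.62 and the pyrimidine median 0.57 below those of controls 1 and 2 on the log2 scale.

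Many genes of translation and energy metabolism fell. Of 53 ribosomal protein genes, 42 fell and 1 rose (46 and 1 adjusted over the list alone), with a median log2 change of -0.58, and rpmD (1.99-fold) and rplL (1.91-fold) were the largest falls. The gene that rose was rplI (0.44). Of 14 genes of translation factors and RNA polymerase, 8 fell (8 adjusted over the list alone), with frr 1.74-fold and tsf 1.68-fold lower, and 5 fell without control 2. By camera these lists gave adjusted p values of 1.23e-08 and 0.0231, and both had adjusted p = 0.620 with an estimated correlation. Of 9 ATP synthase genes, 7 fell (7 adjusted over the list alone), with atpD 1.63-fold lower, and 3 or 4 fell without control 1, 2 or 3 or air plasma 2. Of 12 genes of the citric acid cycle, 8 fell (8 adjusted over the list alone), with mdh 1.85-fold and sdhC 1.68-fold lower, and 4 or 5 fell without control 2, control 3, air plasma 1 or air plasma 2. By camera ATP synthase gave an adjusted p = 0.0243 and the citric acid cycle an adjusted p = 0.0252, and both had adjusted p = 0.652 with an estimated correlation. The call of the citric acid cycle was lost without air plasma 1 (adjusted p = 0.0660) or air plasma 2 (adjusted p = 0.0524). Of 14 genes of glycolysis and pyruvate dehydrogenase, 6 rose and 7 fell (6 and 7 adjusted over the list alone), and the list was not called (camera, adjusted p = 0.435). The pyruvate dehydrogenase genes pdhA and pdhB fell 5.53-fold and 5.51-fold, and pdhC and pdhD 3.18-fold and 3.15-fold. Of 33 genes for carbon sources under CcpA, 4 rose and 14 fell (4 and 15 adjusted over the list alone), with the gluconate genes gntR (3.91-fold) and gntK (3.47-fold), gntP (0.98) and gntZ (0.37) higher and the inositol genes iolH (2.42-fold) and iolI (2.29-fold) lower. The lower CcpA calls numbered 5, 5, 8, 6 and 6 without control 1, control 2, control 3, air plasma 1 and air plasma 2. This list was not called (camera, adjusted p = 0.244), but was without air plasma 3 (0.0453).

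Surfactin synthesis genes and most motility genes fell, while the competence and early sporulation lists held calls in both directions. All 4 genes of the surfactin synthetase operon fell (4 adjusted over the list alone), with a median log2 change of -3.69, and srfAA went from a ratio of 1.59 ± 0.13 to 0.0826 ± 0.0046 (SD, n = 3 each), 19.2-fold lower. The competence gene comS, which lies inside srfAB and is therefore not independent of it, fell by 4.72 ± 0.14 on the log2 scale. The pectate lyase gene pel fell by 3.59 ± 0.10 on the log2 scale. Of 50 motility and chemotaxis genes, 39 fell (41 adjusted over the list alone), with a median of -0.72, including motA (2.27-fold) and the receptor gene tlpA (2.61-fold). The flagellin gene hag had a log2 change of -0.54 ± 0.25 (limma, adjusted p = 0.114), with -0.74 without air plasma 3 (adjusted p = 0.0454, called) and -0.32 without control 3 (adjusted p = 0.272). By camera the surfactin list gave an adjusted p = 1.12e-04, and adjusted p = 0.620 with an estimated correlation. The motility list gave an adjusted p = 1.65e-08 by camera, and adjusted p = 0.652 with an estimated correlation. Of 19 competence genes under ComK, 1 rose and 3 fell (none higher and 2 lower adjusted over the list alone). Among them nucA fell 1.75-fold, nin fell 1.38-fold, and comEC rose 1.19-fold with an adjusted p from 0.0679 to 0.111 without any 1 array other than air plasma 2. The regulator gene comK fell by 0.51 ± 0.15 with an adjusted p of 0.0961, 0.0619, 0.0786 and 0.0544 without control 1, control 2, control 3 and air plasma 2. Of 20 early sporulation genes, 4 rose and 3 fell (3 and 2 adjusted over the list alone), with spo0F (1.53-fold), sigF (1.36-fold), kinA (1.32-fold) and spoIIP (0.31) higher and sigG (-0.58), spoIID (-0.37) and spoIIGA (-0.27) lower. The kinA and sigF calls were lost without any of the 3 controls or air plasma 2, and that of sigF also without air plasma 3 (adjusted p from 0.0544 to 0.114). The higher sporulation calls ranged from 1, without any of the 3 controls or air plasma 2, to 6 without air plasma 1. Neither the competence list (camera, adjusted p = 0.576) nor the sporulation list (0.743) was called.

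At the level of probes, 11856 of 41882 were called by limma, 5883 higher and 5973 lower. Probe log2 changes ran from -5.59 to 7.96. With the preset correlation camera called 25 of the 42 lists, and with a correlation estimated per list it called 0, with 0 at an unadjusted p under 0.05 (lowest p = 0.0562). The set test fry, which does not compare a list with other genes, called 30 lists. Of these, 8 were not called by camera: CssRS and glycolysis (adjusted p = 3.81e-04 each), LiaRS (0.0178), TnrA and GlnR (0.0252), MntR (0.0289), base excision repair and Zur (0.0293 each) and sigma W (0.0432). Several of the largest rises start from control ratios under 0.1, and signal levels were not analysed here, so how near those ratios lie to background is unknown and the size of these folds is uncertain.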

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

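Deviations of air plasma and control arrays of the same number from their group means correlated across genes with r of 0.07, -0.06 and 0.14. Such values do not show pairing over all genes, but cannot exclude it in some of them. In the PBSX, purine and pyrimidine lists control 3 lay below controls 1 and 2. Their medians without air plasma 3 were -0.71, -1.54 and -2.06, against -1.11, -1.83 and -2.92 with all arrays. Replicate 3 may thus share a shift in these lists. With the number as a block, the camera adjusted p was 4.86e-07 for PBSX, 2.85e-06 for purine and 5.87e-04 for pyrimidine genes. With group as the only term it was 0.00640, 2.58e-05 and 0.00441. The block covers all 3 replicate numbers, so it is not a separate test of replicate 3. In that fit, 1825 genes, 25 lists and 7315 probes were called. Not every array correlated best with its own number.

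Of the 190 genes named by rule or as members 3 and 4 of a list, 149 kept their direction and their side of the threshold under all alternatives that were run on them. With 1 array left out, called genes ranged from 1503 to 1966, higher calls from 800 to 994, lower calls from 690 to 1003, at least 2-fold higher from 347 to 418, at least 2-fold lower from 176 to 233, probes from 6853 to 9812 and lists from 21 to 27. The stricter criteria call fewer genes by construction: 447 (316 higher, 131 lower) in the test against a minimum fold, 1277 (687 higher, 590 lower) at an adjusted p under 0.01, 601 (394 higher, 207 lower) at 2-fold and 1212 (669 higher, 543 lower) at 1.5-fold. With an estimated correlation 0 lists were called, and only 3 lists kept their verdict under all alternatives. These were HrcA, ICEBs1 and early sporulation, none of which camera called with all arrays, so no called list kept its call throughout. Gene counts stayed within 1.5 times under quantile normalization (2101), median centring (2057), robust priors (2043), array weights (2549) and the equal-variance test (1786). So did gene counts without genes at exactly 1 (2053), and probes without exact 0 values (12540). With the pseudocount the gene count was 1976, also within 1.5 times. The pseudocount of 16 is large beside the array medians of 1.02 to 1.05, so that fit runs nearly on linear ratios. The count of 1976 therefore does not show how far calls depend on low ratios.

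Signs turned only in results that had not been called, and the cause was not tested. With 1 array left out the log2 change of sigW ranged from -0.042 (without air plasma 2; -0.033 without control 3) to 0.067, and it was -0.31 after quantile normalization. That of hisD ranged from -0.023 (without air plasma 1) to 0.384. The median of the histidine list ranged from -0.025 (without air plasma 1) to 0.346, and that of the competence list from -0.239 to 0.0539, with the direction of its test turned without control 3 (0.0466). The median of the sigma W list was -0.20 after quantile normalization. With 1 array left out, the medians of 4 further lists changed sign. Their ranges were -0.072 to 0.168 for HrcA, -0.781 to 0.060 for TnrA and GlnR, -0.037 to 0.066 for early sporulation and -0.031 to 0.047 for ICEBs1. The Zur list was called higher by fry with its median at -0.26.

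Combining probes into genes, filters on low levels and an intensity trend were not run, because probes are not paired with genes here and no signal levels were analysed. The distance of low ratios from background therefore limits what large folds show.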

Other observations

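Along the chromosome, changes came in runs of neighbouring genes, all named here after their values were seen. There were 37 runs of at least 4 neighbours that were each called and changed at least 2-fold in 1 direction, and the longest held 13 genes, where the longest in 1000 shuffled gene orders held 6. That run fell, from the RNA helicase gene deaD through the yxi genes to wapA, which encodes a cell wall-associated toxin, with a median log2 change of -2.16. Outside the lists, the 4 genes of the osmoprotectant transporter opuC rose (median 1.92), as did the 5 genes from yurU to yurY, which assemble iron-sulfur clusters (median 1.58). The fructose transport genes levG to levD fell (median -1.56), as did the 4 genes from bdbB to sunT (median -1.92), which lie at the genes of the peptide sublancin, and the ykoC to ykoF genes (median -1.74). Within SPbeta, 7 neighbours from yoqG to yoqA rose (median 1.36), while the bdbB to sunT genes of the same prophage fell.

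The tests of general amino acid shortage, of control 3 and of the make-up of the pool, except the test of neighbouring genes, were chosen after the results were seen, and the trpS and neighbouring-gene tests before. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only the real split, 1 of 10, reached 2049 genes, and the highest other split gave 3. For probes the real split, 1 of 10, gave 11856 and the highest other 1. For lists the real split, 1 of 10, gave 25. The other splits gave 14 to 24 lists, the highest with controls 1 and 2 and air plasma 3 against the rest. Camera at its preset correlation thus called many lists even in splits with at most 3 called genes. Each other split keeps part of the difference between the groups, since it sets 2 arrays of a group against 1, so it is no reference without change.

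Tryptophan synthesis genes rose by a median of 7.23. A shortage of all amino acids is argued against. Of the 28 genes of the histidine, arginine and branched-chain lists, 0 were called higher and 6 lower. Cysteine genes rose, so a shortage of some other amino acids stays open. The genes aroE, tyrA and hisC also rose. They stand in 1 run of higher neighbours with the tryptophan genes, so their rise is not separate evidence. A shortage of charged tryptophan tRNA is a candidate explanation, and the synthetase gene trpS, whose leader reads that tRNA, rose by 1.73 ± 0.26, above all other T-box synthetase genes tested, of which tyrZ was highest at 0.69 and the median was -0.24. The anti-TRAP gene yczA (3.28) and the TRAP-controlled genes pabA (1.28) and yhaG (trpP, 1.23), looked up afterwards, rose too. Whether plasma destroyed tryptophan in the medium, impaired its charging or acted on the regulators was not tested.

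Control 3 stood above the other controls in cysteine genes, and its ratios of yxeK (2.49) and ytlI (3.65), named after their values were seen, exceeded those of the other controls (0.0898 to 0.127) and each lay above all 3 air plasma values of its gene (1.48 to 2.50 over both). Carry-over of treated cells or RNA is argued against, since the 15 most raised genes imply a median of -0.10% of treated signal in control 3, at most 0.156%, where the called cysteine genes imply a median of 25.9%. All genes shifted by a median of -0.037, which scaling before deposit can fix, so this value alone does not test the scaling of the array. The 24 called cysteine genes shifted by 0.916 and all 31 by 1.52. They thus stood apart from the other genes of the same array, which a common factor would not give. Sulfur supply in that culture, such as a later growth stage, may have differed from the other controls, which these 2 tests leave open.

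Some genes lay far from a ratio of 1 in every array, although the pool is described as equal amounts of all samples. A pool of only these 6 RNAs is argued against, because 6.16% of genes had a mean of the 6 ratios below 0.5 (176 genes) or above 2 (77 genes). Bias acting on each gene independently of its neighbours is argued against as well. The 96 genes with all 6 ratios below 0.5 formed 55 neighbouring pairs, where 10000 shuffled orders gave at most 10. Shuffling breaks up operons, so this test cannot address a bias that neighbours share. The pool may hold RNA of other conditions. Of the 35 sigma W genes, 34 were among these 96, against 62 of the other 4070 genes. Fisher's exact test gave p = 1.75e-57, with genes taken as independent, which neighbours are not. The transporter gene mtlA, named after its values were seen, was also low, with ratios of 0.0439 to 0.0803. Without a dye swap, a bias shared by neighbours stays open, whether regional or through signal levels, which were not analysed here.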
